A study of Mus musculus with 9 samples.

How the data were processed

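The 9 samples were whole mouse colons, profiled on Affymetrix whole-genome mouse expression arrays, with 1 array per sample. Per the labels, 5 arrays came from animals that carried loxP-flanked Ptch1 alleles and a tamoxifen-inducible Cre at the Rosa26 locus (mutant), and 4 came from animals with the same Cre and unmodified Ptch1 (wildtype). Both groups were injected with 1 mg tamoxifen on 5 consecutive days and the colons were taken at day 12. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase treatment, and 100 ng was labelled with biotin by in vitro transcription. The mice were of a mixed C57BL/6 and Balb/c background. The labels do not state that each sample came from a separate animal. The p-values measure the spread between these samples, which may in part be technical.

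The deposited values were probe set intensities on a linear scale, made with Affymetrix Expression Console 1.1 per the submitters' processing notes. The summary algorithm, the background correction and any filter are not given in the sources used here. The values spanned 5.21 to 23117, and the medians of the 9 arrays lay between 53.8 and 54.7, so the authors' values were already level between arrays and no further normalization was applied. Detection calls were not used here. The number of arrays limits the precision.

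Of 45101 probe sets, 64 controls were left out of all tests. The platform annotation gave 1 gene symbol to 34945 probe sets, several to 932 and none to 9160. A gene identifier was matched in the mouse RefSeq gene table for 34741 of those with 1 symbol, and 0 symbols had to be renamed. No gene was named from a probe set with several symbols. A gene was represented by the probe set with the highest mean over the 9 arrays among those with 1 symbol, which gave 18193 genes. Chromosome positions are not printed, because no genome build belongs to these values.

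Values were tested as log2(intensity + 16), and every fold change is on that scale, which understates the change of dim probe sets. Mutant and wildtype arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend, not robust, 7 residual and 2.45 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. A set of 42 gene lists with 700 memberships, of which 639 were measured, was fixed before the data were examined. The 39 lists with at least 4 measured members, other than the sex-linked genes, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists. Camera was repeated with an estimated correlation, and fry was run as another test. List members without a row of their own were not analysed here.

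Checks of the row names showed that rows carrying 1 gene name shared the strength of the difference between the groups. They did not share its direction and hardly shared the level of signal (values are in the results). This changed how named genes are reported. For a named gene or list member, only whether its row passed the test is given, with the adjusted p, and no direction or fold, except for the Hedgehog target genes, whose rows are printed in full as a check. The rule for named genes, fixed before the data were examined, took all measured Hedgehog target genes with every probe set, the 10 largest rises and 10 largest falls with non-overlapping groups, up to 3 members of each list with the smallest p, and the sex-linked genes. The names of the largest rises and falls are left out, since a name and a fold cannot be tied together here. Names of list members are given for the lists where a group of changed genes was called and for a few others. Camera and fry's one-way test use the sign of each row, so their list results carry the same limit.

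After this was found, a list test that ignores direction was added. It ranks all genes by the absolute moderated t and compares list members with all other genes (cameraPR on ranks, preset correlation 0.01, adjusted over the 39 lists). It was repeated with estimated correlations, with the mean rank over all probe sets of a gene, and with Fisher's exact test on the counts past the threshold. Agreement between rows of 1 gene was measured on the first 2 probe sets of each of 9010 genes, with 100000-resample permutation tests. Levels were compared again after taking off the mean level of rows at a like rank of absolute t, in 100 equal bins.

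Alternatives fixed before the data were examined were the mean over all probe sets of a gene, each probe set separately (45037 tested), leaving out dim genes, eBayes with trend and robust, array weights, quantile normalization, centring on array medians, array number as a covariate, a score of the rows labelled Xist minus Y-linked genes as a covariate, pseudocounts of 1 and 64, stricter thresholds, and leaving out each array in turn. Log2 without a pseudocount was added later. Results were recomputed for 100 of the 126 ways to split the arrays 5 against 4.

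The gene test was tried on simulated data with the means and spread of these 18193 genes and 200 changed genes. It recovered 77% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1, and 5.43% of its calls were unchanged genes. The noise was independent between genes and arrays, with no effect of array number. The median size of the changed genes in the data, 0.37, was below both simulated sizes. These shares therefore need not hold for the data. A separate simulation, with invented levels, gave both rows of a gene the same effect. Its values follow from these settings and do not tell what intact rows of this array would show. With correct names, its mean levels of 2 rows of a gene correlated at 0.798. Of its pairs at an unadjusted p under 0.05, 99.0% had the same sign. With names joined in the order of the test result, the level correlation was 0.00118, the correlation of the rank of absolute t was 0.332, and 49.1% had the same sign. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.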

Results

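Whole colons were profiled on 9 arrays, 5 from mutant and 4 from wildtype samples. Ptch1 encodes the receptor that holds the Hedgehog pathway off in the absence of ligand, and in the mutants its exons 8 and 9 were deleted body-wide by tamoxifen-induced Cre. Array numbers in the sample titles were on average 4.2 for mutants and 8 for wildtypes, so array number and group were partly tied.

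The comparison of mutant with wildtype colons addresses which colon transcripts differ at day 12 of a deletion meant to activate Hedgehog signalling. Of 18193 genes tested, 1474 (8.10%) differed between mutant and wildtype colons at an adjusted p under 0.05 by limma, 800 of them higher and 674 lower in the mutants. Each gene is the brightest row of its name, and brighter rows passed more often. Tested separately, 5.19% of probe sets with 1 gene symbol passed. The changes were small. The median size among the changed genes was 0.37 on the log2 scale, with quartiles of 0.27 and 0.53, and 286 genes changed at least 1.5-fold. At least 2-fold changes were seen in 49 genes, 28 higher and 21 lower. The largest rise was 2.06 (SE 0.50) and the largest fall was -2.23 (SE 0.59) on the log2 scale (n = 5 and 4). Mutant and wildtype arrays overlapped for this fall but not for this rise. The largest fall without overlap was -1.95 (SE 0.47).

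In 1328 of the 1474 changed genes, all 5 mutant arrays lay beyond all 4 wildtype arrays. Over all genes tested this held for 2075 (11.4%), where chance gives 1.59%. With array number as a covariate, 33 genes passed, of which 30 were among the 1474. Without wildtype replicate 3 the count was 386, without wildtype replicate 4 it was 459, without mutant replicate 3 it was 676, without mutant replicate 2 it was 710 and without wildtype replicate 2 it was 850. The count was 1106 without mutant replicate 1 and 1224 without mutant replicate 5. It was higher than 1474 without wildtype replicate 1 (1766) and without mutant replicate 4 (1683), the arrays numbered 5 and 6. With array weights, 2605 genes passed.

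The arrays were close to each other, with correlations across probe sets between 0.986 and 0.997. The first principal component held 41.1% of the variance. Mutants scored between -22.1 and 0.886 on it and wildtypes between 2.49 and 22.1, so the groups did not overlap, but mutant replicate 5 and wildtype replicate 1 lay next to each other. These are the arrays numbered 7 and 5, where the order of numbers crosses the groups. Scores followed array number within the wildtypes (2.49, 18.3, 21.3 and 22.1 at numbers 5, 8, 9 and 10) and among mutants at numbers 4, 6 and 7 (-22.1, -8.34 and 0.886), while mutants at numbers 1 and 3 scored -14.0 and -20.6. The second component held 14.4%.

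**Figure D1:**
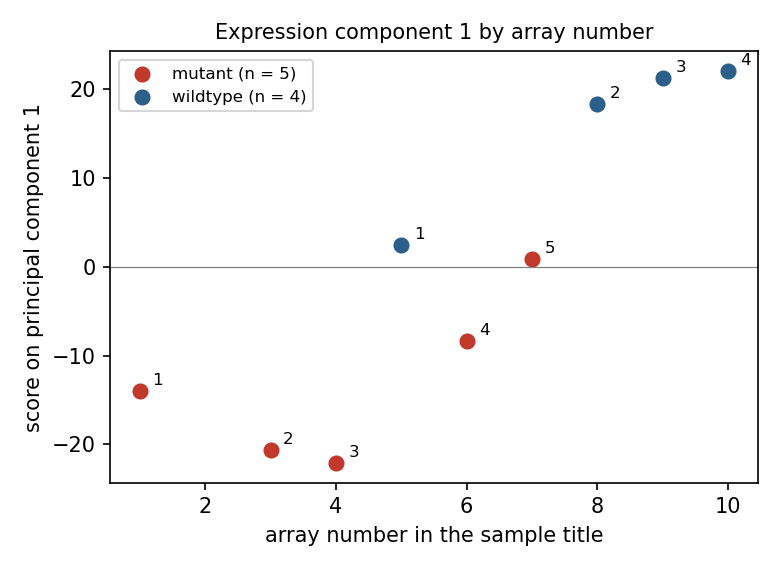
Score of each array on the first principal component of log2 intensities (vertical axis, no unit) against the array number in its title (horizontal axis), with mutants in red and wildtypes in blue and replicate numbers beside the points. The 5 mutants lie at or below 0.886 and the 4 wildtypes at or above 2.49, and array number and group are partly tied.

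Genes that Hedgehog signalling transcribes directly were examined first, as a check on the samples and on the row names. The row used for Gli1, a transcription factor of the pathway and its most common readout, was 0.55 higher in mutants on the log2 scale (SE 0.19, limma adjusted p = 0.116, 0.049 with array weights). The row used for Ptch1 itself was 0.52 higher (SE 0.14, limma adjusted p = 0.0555, past the threshold in 6 of 21 other settings), and its other 2 rows differed by -0.31 and -0.06. Nothing in the sources used here places these Ptch1 probe sets within exons 8 and 9, so they check nothing about the deletion. Hhip, which encodes a secreted decoy receptor for Hedgehog ligands, had 4 rows. All 4 passed when probe sets were tested separately (limma adjusted p from 0.0122 to 0.0124), 3 of them higher in mutants, by 0.62 (SE 0.09), 0.44 (SE 0.06) and 0.70 (SE 0.10), and the fourth lower, by -0.58 (SE 0.08). Of the 3 measured target genes, 1 passed over all genes and 3 when adjusted over the list alone. The strength of the difference was thus shared between the Hhip rows and its direction was not. With array number as a covariate, the adjusted p of Hhip was 0.0982 and its log2 fold change was 0.56.

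The same held across the array. Over 9010 genes with at least 2 probe sets, the rank of the absolute t correlated at 0.243 between the first 2 rows of a gene (permutation p = 1e-05, the smallest these permutations can give). The mean log2 levels of the same rows correlated at only 0.0259 (permutation p = 0.0135), and their signed t at 0.0134. Genes are not independent replicates in these correlations. Where the first row passed the test, the second passed in 25.1% of cases, against 3.50% where it did not. Where both passed, 71 of 134 pairs had the same sign (53.0%, exact 95% interval 44.2 to 61.7). At an unadjusted p under 0.05, 399 of 808 pairs did (49.4%, 45.9 to 52.9). Rows of 1 control transcript, named in the deposited table itself, were closer in mean log2 level than rows of shuffled controls, with an intraclass correlation of 0.275 over 61 rows of 14 transcripts (one-sided permutation p = 0.0102). Their probe sets differ, so no common level is needed. Intensities still ranged widely within a transcript, from 9.32 to 908 over 4 Cre rows, 19.4 to 123 over 4 BioC rows and 20.1 to 183 over 3 actin rows. The rank of the absolute t of the 61 control rows had an intraclass correlation of 0.741 (one-sided permutation p = 1e-04, the smallest these permutations can give). The Xist and Y-linked rows carried the same doubt about level, and none of these 4 genes passed the test, so they do not tell the sex of the animals. Row names therefore carry in part how strongly a gene differed between the groups. They carry little of its level, with the correlation of 0.0259, and no direction that could be seen. The genes below are reported as changed or not, with no direction. Each such call is of the row that carries the name, and for a single gene it is uncertain.

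**Figure D2:**
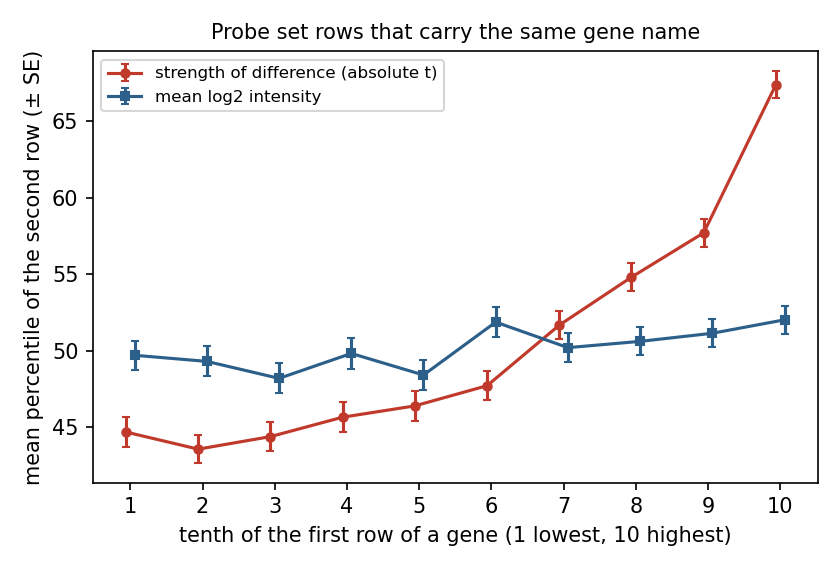
Mean percentile (± SE) of the second row of a gene, with the first rows sorted into 10 equal ranges, for the absolute t between mutant and wildtype (red circles) and for the mean log2 intensity (blue squares), over 9010 genes. For the absolute t the second row averages the percentile 44.7 in the lowest range and 67.4 in the highest, and for the intensity 49.7 and 52.0.

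By the rank test, the members of 10 gene lists ranked higher by the strength of the difference than other genes did, with the cell cycle and cholesterol lists at the head. This test compares ranks of the absolute t, ignores direction and was added after the data were seen. Its estimated correlations come from the rows that carry the names, so they may miss how the named genes move together. By Fisher's exact test on the counts of changed genes, 5 of these 10 were called: cell cycle, cholesterol, interferon, unfolded protein response and absorptive colonocytes. Of 26 measured cell cycle genes, 14 changed (adjusted p = 2.80e-06 by the rank test, 4.89e-04 with an estimated correlation), and 21 did when adjusted over the list alone. Among them were the mitotic kinase Plk1 (limma adjusted p = 0.00222), the spindle motor Kif11 (0.00473) and the cyclin-dependent kinase Cdk1 (0.00931). Of 16 measured genes of cholesterol synthesis and sterol regulation, 11 changed (adjusted p = 1.89e-05, 4.89e-04 with an estimated correlation), and 13 did when adjusted over the list alone. They included Fdps, which makes farnesyl pyrophosphate (limma adjusted p = 0.0091), squalene epoxidase Sqle (0.00958) and squalene synthase Fdft1 (0.00995).

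Interferon-stimulated genes changed in 6 of 19 members (adjusted p = 8.66e-04 by the rank test, 10 when adjusted over the list alone), led by the transcription factor Irf1 (limma adjusted p = 0.013), Oasl2 (0.019) and the GTPase Irgm1 (0.0277, lost in 7 of 21 other settings). Antigen presentation genes changed in 2 of 14 (adjusted p = 0.0156, 7 when adjusted over the list alone), the immunoproteasome subunit Psmb9 (limma adjusted p = 0.019) and the class I light chain B2m (0.0455, lost in 13 of 21 other settings), while the class II regulator Ciita was at 0.0794. Genes of the unfolded protein response changed in 7 of 17 (adjusted p = 0.00657, 12 when adjusted over the list alone). Their leading members were endoplasmic reticulum chaperones and folding enzymes, Pdia6 (limma adjusted p = 0.00736), Hsp90b1 (0.00945) and Calr (0.0103).

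Epithelial and metabolic lists followed. Genes of absorptive colonocytes changed in 6 of 22 (adjusted p = 0.0321 by the rank test, 10 when adjusted over the list alone), among them the monocarboxylate transporter Slc16a1 (limma adjusted p = 0.00973), the water channel Aqp8 (0.0105) and the phosphate transporter Slc20a1 (0.028, lost in 6 of 21 other settings). Ion and water transport genes changed in 4 of 17 (adjusted p = 0.0321, 8 when adjusted over the list alone), led by the sulfate transporter Slc26a2 (limma adjusted p = 0.0089) and the sodium-proton exchanger Slc9a2 (0.0132), and Aqp8 is in this list too. The call for ion and water transport was lost with an estimated correlation (adjusted p = 0.0649 with an estimated correlation), and the other 9 held. With the row names in doubt, those 9 calls do not show that genes moving together were allowed for. PPAR targets and fatty acid oxidation genes changed in 5 of 17 (adjusted p = 0.0321, 7 when adjusted over the list alone), including Cpt1a, which admits fatty acids to mitochondria (limma adjusted p = 0.00975), Acadm (0.0162) and the receptor gene Ppara (0.0165). Glucocorticoid-raised genes changed in 4 of 12 (adjusted p = 0.0321, 8 when adjusted over the list alone), with the metallothioneins Mt2 (limma adjusted p = 0.00995) and Mt1 (0.0314, lost in 7 of 21 other settings) and the leucine zipper gene Tsc22d3 (0.012). Ribosomal protein genes changed in 3 of 12 (adjusted p = 0.036, 4 when adjusted over the list alone), which were Rps20 (limma adjusted p = 0.0133), Rps14 (0.0133) and Rps3 (0.0231). With the mean over the probe sets of a gene, Ppara, Rps20, Calr, Cpt1a, Fdft1 and Lgr5 lost their calls, with adjusted p up to 0.991. With array number as a covariate, 33 of the 38 named genes had another call, while the rank test called 9 lists, 7 of them among these 10. PPAR targets were called in 10 of 22 other settings, ion and water transport in 14, ribosomal proteins in 15, antigen presentation in 17, absorptive colonocytes in 17 and glucocorticoid-raised genes in 18. Absorptive colonocytes lost their call with array weights and without mutant replicates 3 or 4 or wildtype replicates 1 or 2.

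**Figure D3:**
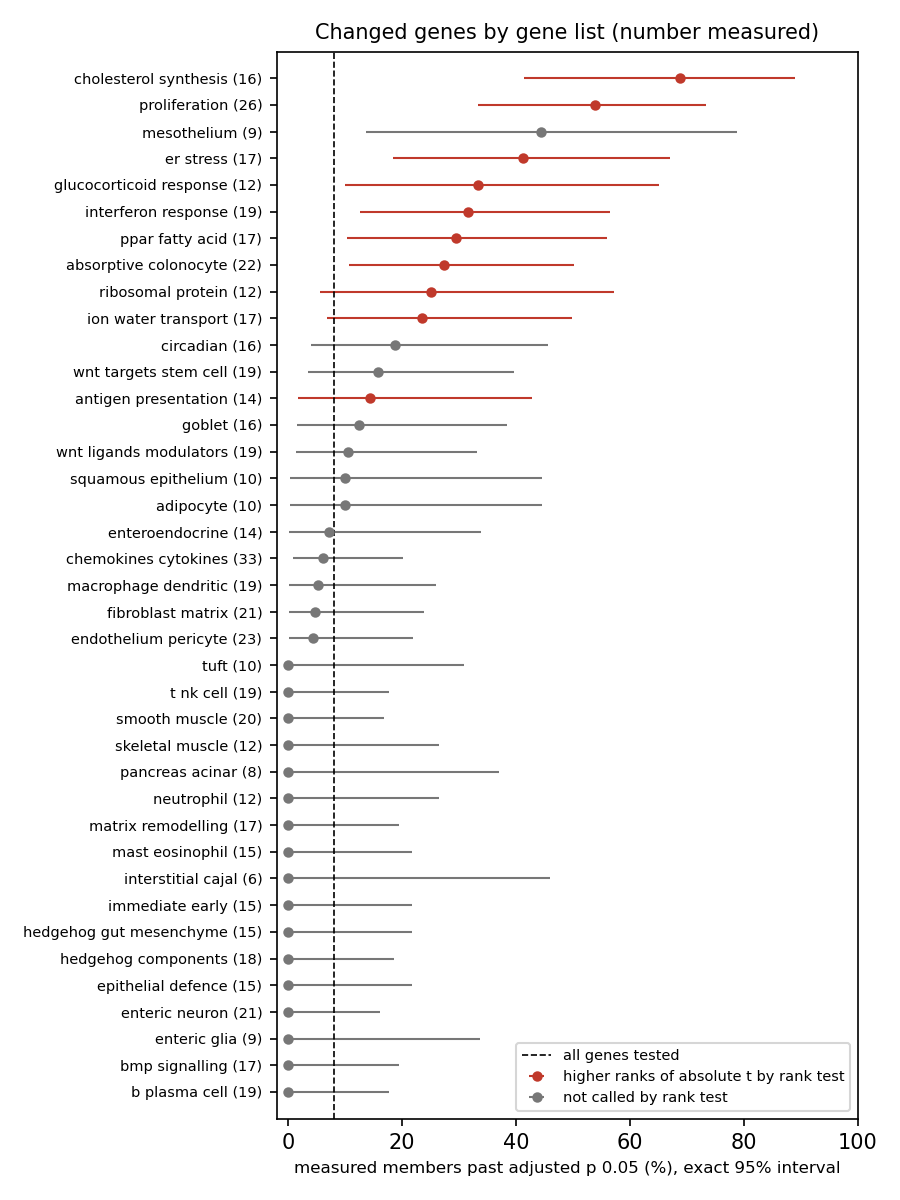
Share of measured members of each of 39 gene lists past an adjusted p of 0.05 (horizontal axis, percent, with exact 95% binomial intervals), the number measured in brackets, and the share over all genes (8.10%) as a dashed line. Red lists are the 10 whose members ranked higher by the absolute t in the rank test, and the shares reach 68.8% for cholesterol synthesis and 53.8% for the cell cycle.

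The stem cell, Wnt, goblet and enteroendocrine lists were not called by the rank test. Epithelial stem and precursor genes and Wnt targets changed in 3 of 19 (rank test adjusted p = 0.558, 4 when adjusted over the list alone), namely Smoc2 (limma adjusted p = 0.0116), Prom1 (0.0126) and the stem cell receptor Lgr5 (0.0257, lost in 7 of 21 other settings). Wnt ligands and their secreted modulators changed in 2 of 19 (rank test adjusted p = 0.986, 3 when adjusted over the list alone), led by the antagonist family member Dkk2 (limma adjusted p = 0.0208, lost in 5 of 21 other settings). Goblet cell genes changed in 2 of 16 (rank test adjusted p = 0.534, 2 when adjusted over the list alone), led by the secreted peptide Spink4 (limma adjusted p = 0.00801). Enteroendocrine genes changed in 1 of 14 (rank test adjusted p = 0.643, 1 when adjusted over the list alone). This was the peptide hormone Pyy (limma adjusted p = 0.0198, lost in 4 of 21 other settings).

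The pathway, stromal, muscle, vessel and enteric nervous system lists each had 0 or 1 gene past the threshold, unlike mesothelium, a serosal lining, with 4 of 9. Of 18 ligands, receptors and transducers of the Hedgehog pathway 0 passed and 1 was at an unadjusted p under 0.05, and of 15 mesenchymal genes reported to follow Hedgehog signalling in the gut 0 passed and 1 was at an unadjusted p under 0.05. BMP ligands, antagonists and targets passed in 0 of 17 (3 at an unadjusted p under 0.05), smooth muscle genes in 0 of 20 (4), matrix remodelling genes in 0 of 17 (2) and interstitial cell of Cajal genes in 0 of 6 (1). Fibroblast and matrix genes passed in 1 of 21 and endothelial and pericyte genes in 1 of 23. Enteric neuron genes passed in 0 of 21 (2 at an unadjusted p under 0.05) and enteric glia genes in 0 of 9 (2). None of these lists, mesothelium included, was called by the rank test. No list was called as ranking lower than other genes. Among lists that leaned lower, the smallest rank test adjusted p was 0.153, for T and natural killer cell genes. When adjusted over the list alone, the counts were 0, or 1 for fibroblast and endothelial genes and 6 for mesothelium. The exact 95% interval for smooth muscle, 0 to 16.8%, still includes the share over all genes.

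Immune cell lists were not called by the rank test. T and natural killer cell genes passed in 0 of 19 (0 at an unadjusted p under 0.05), B and plasma cell genes in 0 of 19 (1), neutrophil genes in 0 of 12 (3) and mast cell and eosinophil genes in 0 of 15 (2). Macrophage and dendritic cell genes passed in 1 of 19 (4 at an unadjusted p under 0.05) and chemokines and cytokines in 2 of 33 (12). Over all genes 4325 of 18193 were at an unadjusted p under 0.05. For the immune lists with 0 past, the exact 95% intervals reach 17.6% to 26.5% and include the 8.10% over all genes. When adjusted over the list alone, the counts were 0, 1 for macrophages and 2 for chemokines. Tuft cell genes passed in 0 of 10 (1 at an unadjusted p under 0.05), epithelial defence genes in 0 of 15 (4) and immediate early genes in 0 of 15 (7). Among tissues that can be carried along with a colon, pancreas genes passed in 0 of 8 (1) and skeletal muscle genes in 0 of 12 (1). Red blood cell genes were not tested as a list, with 0 of 3 past.

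In the test that uses direction, 0 of the 39 lists passed by camera, with a smallest adjusted p of 0.456 and 4 lists at an unadjusted p under 0.05. With an estimated correlation 0 passed as well. By fry, which does not compare a list with other genes, 3 lists moved one way on balance (chemokines and cytokines, interferon-stimulated and immediate early genes, each at an adjusted p of 0.0414) and 27 changed in either direction. These directional tests rest on the sign of each named row.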

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

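In this part, the test of the split by array number and the count of splits for changed genes were set out after their results were seen. The fits with array number and of separate probe sets were fixed before the data were examined. One result came from data outside the comparison of genes. Among 10092 probe sets without a single gene symbol, 214 passed when probe sets were tested separately (2.12%), against 5.19% of those with 1 symbol. In the array medians, the first 2 components and the Hedgehog target rows, no array's gap to its nearest neighbour passed Dixon's 95% value for its group. The nearest to it was wildtype replicate 1 on the first component, at 2.49 against 18.3 to 22.1 for the other wildtypes, a gap of 0.809 of the range, just under that value.

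The first pattern weighed is the number of changed genes. Of 100 splits of the 9 arrays, only the real one called as many genes, with 1474 against 119 in the highest other split. Chance is thus an unlikely source of the count, though 100 splits cannot exclude it. That highest other split set the 4 highest array numbers against the 5 lowest, which exchanges mutant replicate 5 and wildtype replicate 1, and its 119 calls argue against a steady drift with array number as the whole cause. The split does not address an effect of blocks of array numbers. The exchanged arrays lay next to each other on the first component (0.886 and 2.49). With array number as a covariate 33 genes passed. All 1474 genes kept their sign, which their selection for a difference in these same data favours. Their median size went from 0.37 to 0.32 on the log2 scale, and the median SE of all genes from 0.068 to 0.088. Array number and mutant group correlated at -0.68, so this fit cannot tell lost precision from an effect of array number. A partial contribution of array number and an effect of blocks of array numbers stay open. So do a litter or cage difference and a shift in the cell makeup of the colon. All of these stand beside the Ptch1 deletion that the design names. Litter, cage and blocks of array numbers were not tested. Cell makeup was looked at only through named lists, whose rows do not give a direction.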

How the results depend on the processing

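The alternatives were fixed before the data were examined, except log2 without a pseudocount and all tests of lists by rank, which were chosen after. Tested separately, 2029 of 45037 probe sets passed, which counts rows and not genes. The count of 1474 changed genes stayed within 1.5 times with the mean over probe sets, without dim genes, and with trend and robust. It also did after quantile normalization or centring and with the pseudocounts tried. The same held with the score of the rows labelled Xist and Y-linked genes, which is no measure of sex here. It was 2605 with array weights and 33 with array number as a covariate; 286 genes also reached 1.5-fold and 162 an adjusted p under 0.01, as stricter thresholds must. Leaving out 1 array gave 386 to 1766 genes. Fewer arrays can be one reason for the lower counts. They do not account for 1766 without wildtype replicate 1 or 1683 without mutant replicate 4. The share of changed genes that were higher lay between 52.0% and 56.8% except with array number (66.7%). Camera called 0 lists in every fit, those without 1 array included, against 3 by fry's one-way test. The rank test called 10 lists; it called 12 with the mean rank over probe sets, 6 with the mean over probe sets, 6 with array weights, 6 by Fisher's exact test and 5 to 11 without 1 array (5 without wildtype replicate 1, 6 without mutant replicate 3 and 6 without mutant replicate 4); the cause was not tested. Cell cycle, cholesterol and interferon lists were called in all 22 other settings, the unfolded protein response in 21 and PPAR targets in 10. All settings use the same named rows. If names follow the real test, a candidate explanation weighed below, these counts are no independent check of the lists. Of 38 named genes, 33 had another call with array number, 12 without wildtype replicate 3, 11 without wildtype replicate 4, and at most 7 in any other setting. Of the dimmest 10% of genes 0.275% changed; how far signal over background limits them was not tested.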

Other observations

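The splits by camera and by the rank test of lists, and the test of levels left after the rank of absolute t, were set out before their result was seen, and the other tests in this part after. Some other lists were not called by the rank test. Mesothelial genes of the serosa changed in 4 of 9 members, 6 when adjusted over the list alone (rank test adjusted p = 0.0855), and the list was called in 6 of 22 other settings, Fisher's exact test on the counts among them. Clock genes, which follow the hour of collection, changed in 3 of 16, 4 when adjusted over the list alone (rank test adjusted p = 0.218). Among the other settings, this list was called only with array number as a covariate and with the mean rank over probe sets. Adipocyte genes changed in 1 of 10 and genes of squamous epithelium in 1 of 10, with rank test adjusted p of 0.44 and 0.924.

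Of 100 splits of the arrays, 1 gave as many lists by the rank test as the real groups, with 10 lists in the real split and 6 in the highest other, but if names follow the real test, a candidate explanation of the last pattern, other splits lose the names and this count says nothing of chance. By camera the real split gave 0 lists and the highest other 1, so all 100 splits gave as many.

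Another pattern weighed is the high share of changed genes in some lists. Brighter rows passed more often: 0.275% of genes changed in the lowest 10% by mean level and 18.1% in the highest 10%. The share in the cell cycle list, 14 of 26, lay above the 18.1% of the brightest rows (one-sided exact binomial p = 4.24e-05), and so did the 11 of 16 cholesterol genes (p = 1.19e-05). Row names carry little of the level, so the abundance of the named genes themselves was not tested. These p-values take genes as independent and are too small where genes move together. Of the other 8 lists called, only 1, the unfolded protein response, passed the same one-sided exact binomial test (p = 0.0225 before adjustment). For antigen presentation the share, 14.3%, lay below the 18.1%. A contribution of abundance stays open for every list called. A hypothesis is that cell cycle and sterol genes respond to the deletion, in a direction these rows cannot give, which gene values with intact names would test.

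The last pattern is that rows of 1 gene shared the strength of the difference but not its sign, and hardly their level. An annotation table wrong in part, as the only fault, would leave the sign shared in 93.0% of pairs past the threshold, if the pairs beyond chance were rightly named, and 53.0% was found (exact 95% interval 44.2 to 61.7). Names joined to values at random are argued against by the correlation of 0.243 for the rank of absolute t. Of 100 splits, 1 gave a correlation as large as the real one, 0.241 with an ordinary t against 0.145 in the highest other, which the next explanation would itself produce, so it says nothing of chance. A candidate explanation is that names and values were joined after sorting by a mutant against wildtype test: the level correlation of 0.0259 between rows of 1 gene and the grouping of control rows would then come from brighter rows having higher absolute t. With the level at each rank of absolute t taken off, the level correlation was 0.011 (permutation p = 0.295) and the intraclass correlation of control rows 0.102 (one-sided permutation p = 0.154), and how the table was put together was not seen.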
